A study of Homo sapiens with 2 samples.

How the data were processed

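Gene expression was measured in HCC15, an established human lung cancer cell line described by the labels as squamous, on biotin-labelled Affymetrix expression arrays. The 2 samples were 1 culture given a control siRNA and 1 culture given an siRNA against CTNNB1, the gene of beta-catenin, and cells were collected 48 h after transfection. The title of the control sample carries the word Tax, the labels do not say what its siRNA targets, and every ratio takes that array as the reference. Cells were kept in RPMI medium with 5% serum, and RNA was extracted on columns with a DNase step, per the labels' protocols.

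The deposited table held 1 linear signal intensity for each of 54675 probe sets on each array, with no log transformation and no missing value. MAS5, which combines the matching and mismatching probes of a probe set into 1 signal, was the tool used by the authors, per the submitters' processing notes. The MAS5 version, the target intensity, any scaling between arrays and the detection calls are not given in the sources used here. The 2% trimmed mean of the deposited intensities was 233 on the control array and 271 on the CTNNB1 siRNA array, and the medians were 51.3 and 46.7, so the 2 columns do not share 1 target over all probe sets.

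Probe sets were named from GEO's platform annotation, which listed 42898 of the probe sets. Of these, 41097 had 1 gene symbol and 1801 had several, and 11777 probe sets of the table were not listed and are unnamed here. Symbols were updated through the Entrez number to NCBI RefSeq gene names, with a match for 41043 of the 41097, and the other 54 kept the annotation's symbol. No genome build is named in the sources, so no coordinates are given.

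From the deposited intensities, log2 ratios were computed as CTNNB1 siRNA over control siRNA with no further normalization. Values under the 25th percentile of all values of both arrays, a signal of 13.8, were set to that floor, and a fold against a floored value is a lower bound. The floor is not a detection limit. A probe set entered when the mean of its 2 signals was at or above the median of all values, 49.1, which 27151 probe sets did. A gene was represented by its entering probe set with the highest mean signal among those annotated to that gene alone, which gave 12531 genes. Probe sets of 1 gene can read different transcripts or overlapping parts of the same one, and probe sets whose names end in _x_at or _s_at can take signal from related genes.

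With 1 array per group there was no replicate, so no test between conditions and no p-value was possible. All differences compare these 2 arrays only, and they contain any difference between the 2 cultures and hybridisations. Genes were called by a fixed rule of size, a difference of at least 2-fold. As a measure of error, the pooled SD of log2 ratios between entering probe sets of the same gene was computed over the 5791 genes with 2 or more of them (15728 probe sets). It was 0.42, and 0.29 over probe sets with a mean signal at or above the 75th percentile. This SD covers probe set error and isoform differences, not variation between cultures. The number of arrays limits the precision.

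Before the data were examined, 26 gene lists, the rule for naming genes and the alternatives were fixed. For each list the median log2 ratio of its entering genes was set against the medians of 10000 random lists of the same size matched on mean signal in 20 bins, and the position is given as a percentile. This describes the 2 arrays and is not a test across samples. A list outside the middle 95% is reported as standing apart, and about 1.3 of 26 lists would be expected there if the genes of a list varied independently. Genes of a pathway can vary together between 2 cultures. More lists than that can therefore stand apart without an effect of the siRNA. Genes named were CTNNB1, the 12 genes with the largest decrease and the 12 with the largest increase among genes past the 2-fold rule, every entering core Wnt target, and up to 4 members of each other list with the largest absolute ratio. For the 2 groups of 12, all entering probe sets of the gene had to go one way and the higher of the 2 signals had to be at or above 209, the 75th percentile. Control probe sets, probe sets with several symbols or none, XIST and Y-linked genes were not named.

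The calculations were tested on simulated arrays in which 200 genes were changed by known amounts, with noise at the probe set SD and 12800 genes entering. The changed genes all had a control signal at or above the 75th percentile, and the noise was the same at all signals. The recovered shares therefore do not cover changes in dim genes. The share of unchanged genes past the rule likewise holds for that 1 noise level and not for dim genes in particular. A true log2 ratio of -2 was called past the 2-fold rule for 98% of 50 genes, -1.5 for 92%, 1.5 for 86% and 2 for 100%, and 1.82% of unchanged genes passed the rule. Alternatives were quantile normalization, scaling to a common median, loess on signal (span 0.3), floors at the 10th percentile and the median, no filter and a filter at the 75th percentile, other rules for the probe set of a gene, thresholds of 1.5-fold and 3-fold, and counting probe sets. Centring on the median ratio was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.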

Results

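The series compared the transcriptome of HCC15 cells after knockdown of CTNNB1 with that of cells given a control siRNA. Its title places the comparison in a search for Wnt target genes in CTNNB1-mutated non-small-cell lung cancer. Each group was 1 array, so every value below is a single measurement without a replicate. Signals ran from 0.1 to 12951 on the control array and from 0 to 14374 on the CTNNB1 siRNA array. Across the 27151 entering probe sets, the log2 signals of the 2 arrays correlated with a Pearson r of 0.964 (across probe sets, which are not independent replicates).

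The targeted transcript was lower on the CTNNB1 siRNA array. The brightest CTNNB1 probe set (201533_at) had a signal of 1224 with control siRNA and 339 with CTNNB1 siRNA, 27.7% of the control and a log2 ratio of -1.85 against a probe set SD of 0.42. A dimmer CTNNB1 probe set (1554411_at) went from 89.8 to 45.8, 51% of the control. The third CTNNB1 probe set (223679_at) read 130 and 118, 91.3% of the control, a difference smaller than the probe set SD. The median of the 3 CTNNB1 probe sets was a log2 ratio of -0.97.

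Established Wnt/beta-catenin target genes had the lowest median of the 26 gene lists. Of the 20 genes on the core list, 14 entered, 7 were at least 2-fold lower with CTNNB1 siRNA and 0 were at least 2-fold higher. NKD1, an inhibitor of Wnt signalling that binds Dishevelled, was 8.42-fold lower (a signal of 296 against 35.1). A second NKD1 probe set (229481_at) went from 294 to 10. SP5, a transcription factor, went from 94.1 to a value under the floor and was at least 6.82-fold lower, although with the floor at the median its log2 ratio, -0.94, did not pass 2-fold. The R-spondin receptor gene LGR5 was 4.3-fold lower (127 against 29.5), although its second probe set (210393_at), under the signal filter, read 39.1 and 51.7. AXIN2, the scaffold protein of the beta-catenin destruction complex and a feedback target, was 3.31-fold lower (906 against 273).

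TNFRSF19 was 2.94-fold lower, although its 2 dim probe sets under the signal filter (223827_at, 29.4 and 37.4, and 224090_s_at, 10.8 and 21.7) went upward, as did 1 of AXIN2 (224498_x_at, 20 and 35.7). The secreted Wnt inhibitor WIF1 was the brightest member, and its signal was 2.59-fold lower (4340 against 1676). NOTUM, a secreted enzyme that inactivates Wnt proteins, was 2.43-fold lower. The other 7 members stayed under 2-fold. Log2 ratios were -0.49 for the ubiquitin ligase RNF43, -0.39 for the Wnt antagonist DKK1, -0.37 for the transcription factor LEF1, -0.21 for NKD2, -0.12 for BAMBI, -0.01 for ZNRF3 and 0.08 for KREMEN1. The signs for BAMBI, ZNRF3 and KREMEN1 were not the same under every normalization.

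The median log2 ratio of the core list was -0.89, below every one of 10000 random lists of matched signal (middle 95% from -0.16 to 0.35). All 14 genes lay below the median of all genes. The list's median was -1.03 after loess and -0.36 after scaling to a common median, where SP5 did not enter (the other 13 genes had a median of -0.49 as deposited), and it stayed under the 2.5 percentile in all 10 alternative settings. TCF7, DKK4, APCDD1, ASCL2, PROX1 and CRIPTO had no probe set that entered under a single symbol. DKK4, APCDD1, ASCL2 and PROX1 entered only with no filter, where the median of the 18 genes was -0.44, and TCF7 and CRIPTO were not analysed here.

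**Figure D1:**
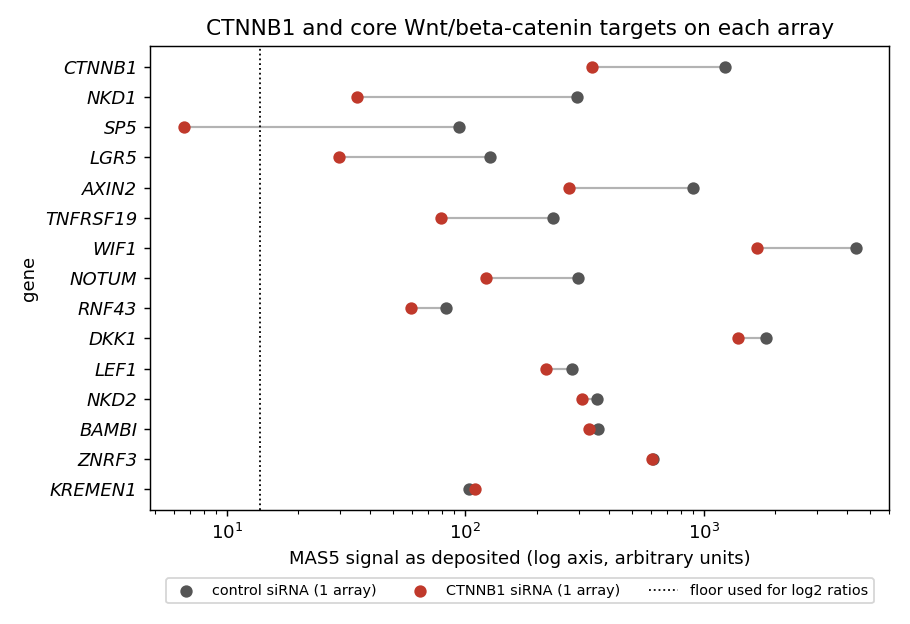
Deposited MAS5 signal (log axis, arbitrary units) of CTNNB1 and the 14 entering core Wnt/beta-catenin targets on the control siRNA array (grey) and the CTNNB1 siRNA array (red), 1 array each, joined by a line per gene. CTNNB1, NKD1, SP5, LGR5, AXIN2, TNFRSF19, WIF1 and NOTUM are at least 2-fold lower on the CTNNB1 siRNA array, and the dotted line is the floor of 13.8 used for log2 ratios.

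Genes reported as beta-catenin targets in a wider set of tissues were not lower as a group. Of 40 such genes, 27 entered, 0 were at least 2-fold lower and 5 were at least 2-fold higher. The higher ones were the urokinase receptor gene PLAUR (2.88-fold), the adhesion receptor CD44 (2.69-fold, from a signal of 61.6 to 166), the AP-1 subunit FOSL1 (2.47-fold), the tight junction gene CLDN1 (2.4-fold) and the AP-1 subunit JUN (2.24-fold, but a log2 ratio of 0.94 after loess and after quantile normalization, under the rule). The other entering CD44 probe sets disagreed, with 51.9 and 56.4 for 204490_s_at and 50.4 and 123 for 212063_at. JUN lies outside the naming rule and was chosen after its value was seen, as were MYC and CCND1. MYC had a log2 ratio of 0.62 and CCND1 of 0.13. The list's median was 0.14, at the 18.2 percentile of matched random lists.

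Among the other Wnt pathway genes, BCL9L, which encodes a coactivator of beta-catenin, was 5.06-fold higher with CTNNB1 siRNA (195 against 986). Its second probe set (228065_at) read 344 and 618, 180% of the control. The list of destruction complex members and TCF cofactors had 25 entering genes, of which BCL9L was the only one past 2-fold. TLE1 (0.66), CSNK1D (0.56) and BTRC (-0.56) followed in absolute log2 ratio. The entering TLE1 probe sets disagreed, with log2 ratios of 0.03, 0.66, 1.03 and, from a control signal under the floor, at least 2.72. This list's median was 0.35, at the 98.1 percentile, and at the 97 percentile with the filter at the 75th percentile, where it no longer stood apart. Of 17 entering Wnt ligand and receptor genes, ROR2 and FZD2 were each 2.1-fold higher, ROR1 (0.83) and FZD5 (0.63) were not past the rule, and the list lay at the 96.4 percentile.

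Across all genes, 298 of 12531 were at least 2-fold lower and 287 at least 2-fold higher with CTNNB1 siRNA, 4.67% in all. On the simulated arrays 1.82% of unchanged genes passed the same rule. That noise was the same at all signals, whereas the measured probe set SD was smaller, 0.29, over bright probe sets. The 1.82% is therefore not the share to expect among dim genes, and 255 of the 298 lower genes lay in the 3 dimmest deciles. The log2 ratios of all entering genes had an SD of 0.48, against the probe set SD of 0.42. A sizeable part of the calls can therefore be probe set error. Among genes with 1 direction over all entering probe sets and a signal of at least 209 on 1 array, which leaves out SP5, LGR5, CHAC1 and TAGLN, the 12 largest decreases besides NKD1, CTNNB1, AXIN2 and TNFRSF19 were in SUSD2, a membrane protein gene (4.52-fold), TESC, a calcium-binding protein gene (4.39-fold), PDK4, a kinase that inhibits pyruvate dehydrogenase (3.46-fold), NREP (3.18-fold), ZBED2 (3.18-fold), LGR6, an R-spondin receptor gene (3.06-fold), SLC27A2, a fatty acid transport and activation gene (3.03-fold), and AKR1C1, an aldo-keto reductase gene with close paralogs (2.97-fold). SUSD2 went from 835 to 185, TESC from 778 to 177 and PDK4 from 945 to 273. Second probe sets read 99.4 and 50.2 for PDK4 (205960_at), 800 and 305 for SLC27A2 (205769_at), 97.7 and 38 for SUSD2 (234310_s_at) and 148 and 19.7 for NREP (201309_x_at). The AKR1C1 probe sets ranged from -1.57 to -0.31, and its median over probe sets, -0.71, did not pass 2-fold.

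Under the same rule, the largest increases were in PTGES, the prostaglandin E synthase gene, which was 5.8-fold higher (384 against 2228), BCL9L, and the cytokine gene IL11 (4.65-fold, 52.2 against 243). COXFA4L3 was 4.37-fold higher, LMNB1, which encodes lamin B1, 4.36-fold (372 against 1620), and the claudin gene CLDN11 4.13-fold. CCN5 was 3.73-fold higher, the HSP90 co-chaperone gene FKBP4 3.72-fold, the basement membrane collagen gene COL4A2 3.72-fold, the cofilin kinase gene LIMK1 3.64-fold, WDR7 3.62-fold and the adenosine deaminase gene ADA 3.57-fold. Second probe sets of PTGES (207388_s_at) and ADA (216705_s_at) read 391% and 291% of the control, those of FKBP4 (200894_s_at) and COL4A2 (211966_at) 210% and 167%. Dim probe sets under the signal filter did not follow for IL11 and LIMK1, and 1 each of CLDN11 and WDR7 went downward. All 12 stayed at least 2-fold higher in all the alternative settings in which they entered, and so did 10 of the 11 lower genes other than CTNNB1, AKR1C1 being the exception.

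The counts of lower and higher genes depend on how the arrays are scaled. The median log2 ratio of all entering genes was 0.15, a 1.11-fold shift upward. The median ran from -0.23 in the dimmest decile of genes to 0.28 and 0.27 in the 2 brightest deciles, and 255 of the 298 lower genes, but 119 of the 287 higher genes, lay in the 3 dimmest deciles. Lower genes made up 50.9% of calls as deposited, 54.4% after loess, 57.4% after quantile normalization, 27.9% after scaling to a common median and 73.5% after centring on the median ratio. The calls of named genes depended on the settings as well. Besides CTNNB1, 17 named genes past 2-fold fell short of it in at least 1 alternative, COL5A1, FZD2, ROR2 and ANKRD37 among them. Another 19 passed 2-fold only in an alternative, such as AURKB (1.07), CENPE (1.03), NFKBIA (1.12), SMURF1 (1.08) and NECTIN2 (1.10) with scaling to a common median. Of 68 named genes with several entering probe sets, 18 had log2 ratios more than 1 apart, and 90 had 1 entering probe set.

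**Figure D2:**
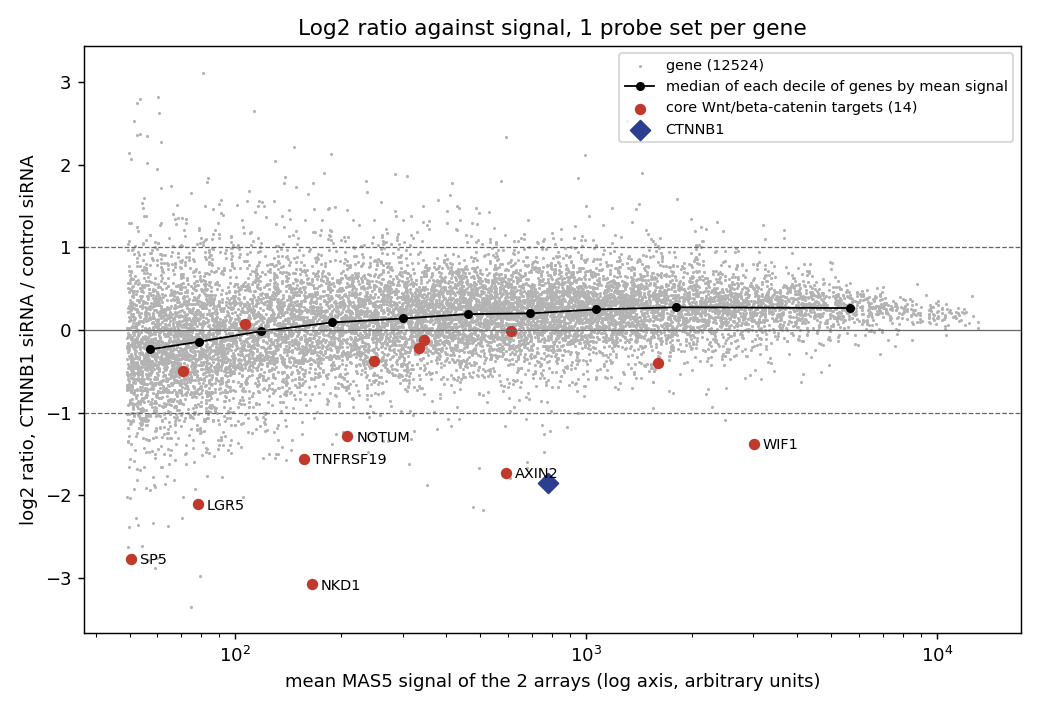
Log2 ratio of CTNNB1 siRNA over control siRNA against the mean MAS5 signal of the 2 arrays (log axis, arbitrary units), 1 grey point per gene (XIST and Y-linked genes are not drawn). The black line joins the medians of deciles of the genes by signal and goes from -0.23 to 0.27; CTNNB1 (blue diamond) and 7 core Wnt targets (red, named) lie below the dashed line at a log2 ratio of -1.

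Mitotic genes were modestly higher as a group with CTNNB1 siRNA. All 26 genes of the G2/M list entered, with log2 ratios from 0.17 to 0.94, and all 26 lay above the median of all genes, although none passed 2-fold as deposited. AURKB (0.94), CENPE (0.90), BUB1 (0.84) and the proliferation marker MKI67 (0.82) had the largest ratios. The list's median was 0.54, above all 10000 matched random lists (middle 95% from 0.16 to 0.36). It was 0.27 after loess, still above all of them, with 2 members below 0. Genes of G1/S and DNA replication did not stand apart. Their median was 0.23 over 25 genes, at the 33.9 percentile, with none past 2-fold as deposited and the largest ratios in UHRF1 (0.80), MCM10 (0.75; 0.05 and 1.36 in its other probe sets), CCNE1 (0.60) and CCNE2 (0.54).

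The list of stress response genes had a low median relative to genes of matched signal, although its members went both ways. Of 21 genes of the unfolded protein and integrated stress response, 4 were at least 2-fold lower and 1 at least 2-fold higher. CHAC1, a glutathione-degrading enzyme gene, was 3.75-fold lower (88 against 23.5), the pseudokinase gene TRIB3 2.77-fold (1119 against 404), VLDLR 2.38-fold and the asparagine synthetase gene ASNS 2.12-fold (3381 against 1593; a log2 ratio of -0.95 with scaling to a common median, under the rule). ASNS lies outside the naming rule and was chosen after its value was seen. A second, dim TRIB3 probe set (1555788_a_at) read 62.2 and 54.3. With the median over its probe sets TRIB3 had a log2 ratio of -0.83, and CHAC1 had -0.84 with the floor at the median, both under 2-fold. The endoplasmic reticulum chaperone gene HSP90B1 was 2.6-fold higher. Of the 21 genes, 13 lay below the median of all genes and 8 above it. Log2 ratios were 0.67 for PDIA4, 0.33 for ATF4, 0.30 for ATF3, 0.16 for HSPA5, -0.01 for DDIT3 and -0.03 for XBP1. These genes were chosen after their values were seen and are not in the counts of named genes. The list's median was -0.03, at the 0.12 percentile. Its sign turned to 0.10 with scaling to a common median, where the list was still at the 0.1 percentile.

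Mesenchymal genes had a median of -0.19 over 15 genes, at the 1.34 percentile. TAGLN (3.67-fold), POSTN (2.24-fold) and COL1A1 (2.02-fold) were lower and COL5A1 was 2.12-fold higher. The list lay at the 5.88 percentile after loess and at the 8.79 percentile with the median over probe sets, so it stood apart in only 6 of 10 alternative settings. Probe sets of TAGLN and COL1A1 disagreed in sign, and COL1A1 had a log2 ratio of 0.05 with the median over its probe sets. Junction genes of the cadherin and desmosome list had a median of 0.07 at the 2.72 percentile over 16 genes, with none past 2-fold. The position depended on the setting, from the 2.01 percentile with the filter at the 75th percentile to 10.2 and 12.7 after quantile normalization and loess, 53.9 with the median over probe sets and 56.1 with the probe set of largest ratio. NECTIN2 had a log2 ratio of 0.97, the E-cadherin gene CDH1 -0.66, PKP4 0.59 and CLDN7 0.40.

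In the deposited scaling the remaining pathway lists did not stand apart from matched random lists, but MYC-associated and interferon genes did in 2 alternative settings each. MYC-associated growth genes had a median of 0.36 over 16 genes (96.8 percentile; 98.2 with the filter at the 75th percentile and 98.5 with the median over probe sets), with RRP9 2.94-fold higher and SRM at 0.63, PA2G4 at 0.57 and NOLC1 at 0.47. NF-kB and inflammatory genes had a median of 0.26 over 13 genes (94.2 percentile), led by NFKBIA (0.99), IL1A (0.79), IL1B (0.73) and CXCL2 (0.64). Interferon response genes had a median of 0.29 over 20 genes (93.2 percentile; 98.5 after quantile normalization and 98.6 after loess). IFIT3 was 2-fold higher (a log2 ratio of 0.77 after loess), OAS1 2.14-fold lower (-0.96 with scaling to a common median), and IFIT1 and IFIT2 had log2 ratios of 0.79 and 0.79. Apoptosis regulators had a median of 0.29 over 16 genes (82.2 percentile), with CASP9 at 0.73, PMAIP1 at 0.35, BIRC2 at 0.35 and BCL2L11 at 0.33 (-0.09 to 1.30 over its 6 entering probe sets).

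Among p53 targets, BAX was 3.44-fold higher from a dim signal of 61.9 and the cell cycle inhibitor gene CDKN1A was 2.34-fold lower, while AEN (0.72) and PLK3 (0.69) stayed under 2-fold. The p53 list had a median of 0.17 over 15 genes (51.8 percentile). In the BMP and TGF-beta list, the receptor gene TGFBR1 was 2.97-fold higher, the ligand gene BMP2 2.53-fold lower (a log2 ratio of -0.84 with the median over its probe sets) and its antagonist NOG 2.26-fold lower. SMURF1 had a log2 ratio of 0.94, and the median of that list was 0.17 over 18 genes (41.8 percentile). YAP/TEAD targets had a median of 0.26 over 15 genes (57.4 percentile), with AMOTL1 at -0.86, NT5E at 0.77, AMOTL2 at 0.63 and AXL at 0.51. Notch pathway genes had a median of 0.22 over 11 genes (65.3 percentile), with MAML1 at 0.64, HES4 at -0.61, NRARP at -0.60 and NOTCH1 at 0.46.

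Hypoxia and glycolysis genes had a median of 0.19 over 19 genes (36.1 percentile). ANKRD37 was 2.09-fold lower, ADM lay just under the rule (1779 against 3556), and PFKFB3 (0.83) and the glucose transporter gene SLC2A1 (-0.70) followed. Cholesterol synthesis genes had a median of 0.12 over 14 genes (12.5 percentile), with NSDHL just under the rule (361 against 719), STARD4 at -0.50, INSIG1 at 0.46 and LSS at 0.36. Stem-cell associated genes had a median of 0.13 over 6 genes (19.5 percentile). In that list the receptor kinase gene KIT was 2.3-fold lower, EPCAM had a log2 ratio of 0.39, ALDH1A1 of 0.28 and NES of 0.17. Housekeeping genes had a median of 0.24 over 12 genes (44.8 percentile), with POLR2A at 0.54, ACTB at 0.41, GUSB at 0.35 and TBP at 0.28.

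Few lineage markers passed the signal filter, and none passed 2-fold. Of 19 squamous markers 5 entered, with a median of -0.11 (16.4 percentile). SFN (5472 against 5009) and PERP (3189 against 3969) were bright, S100A2 read 104 and 126, and SOX2 had a signal of 60.1 and 41.6. Of 15 lung adenocarcinoma and alveolar markers 7 entered, with a median of 0.33 (90.9 percentile; 97.9 after quantile normalization and 97.8 after loess, where the list stood apart) and log2 ratios of 0.83 for SFTPC (1 of 5 probe sets, the others under the floor on both arrays), 0.56 for FOXA1, 0.37 for KRT7 and 0.33 for MUC1. Neuroendocrine markers had a median of 0.13 over 3 genes (58.7 percentile), with CALCA at -0.34, NCAM1 at 0.18 and a bright UCHL1 (7014 against 7653) at 0.13. Fibroblast markers had a median of 0.18 over 6 genes (60.3 percentile), with COL6A1 at 0.76, MFAP5 at 0.37, FBLN1 at 0.25 and DCN at 0.11. Leukocyte markers were dim on both arrays. LAPTM5 had a signal of 95.5 and 63.7, FCER1G of 111 and 80.2, MS4A1 of 62.4 and 46.8 and CD79A of 80.4 and 63.2, and the median of that list was -0.38 over 6 genes (17.6 percentile).

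**Figure D3:**
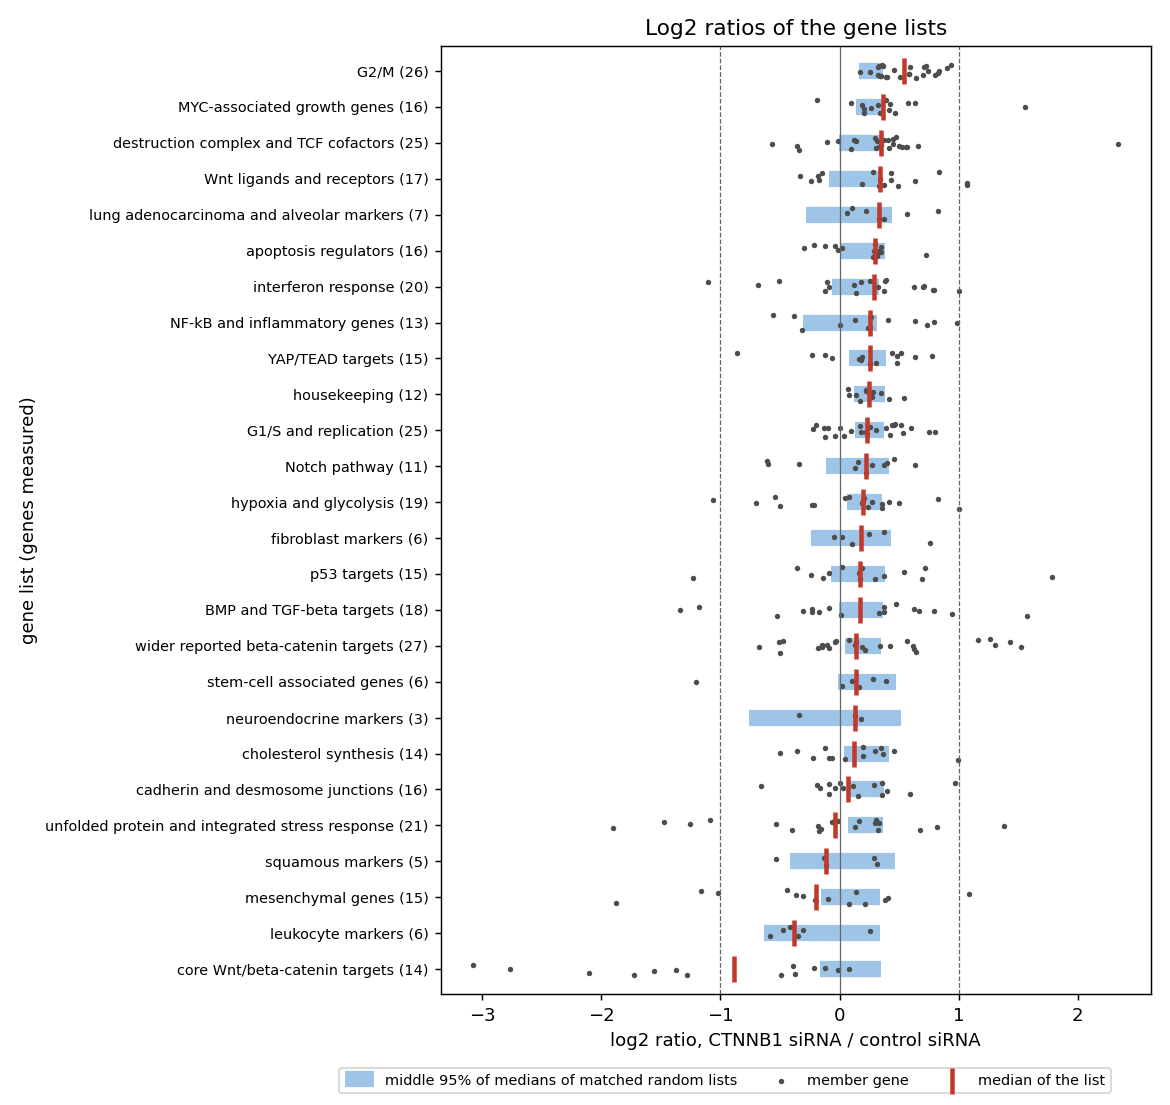
Log2 ratios of CTNNB1 siRNA over control siRNA (x axis) for the members (dots) and the median (red bar) of the 26 gene lists (y axis, number of genes measured in parentheses). Blue bands are the middle 95% of medians of 10000 random lists matched on signal; the core Wnt targets (median -0.89) lie far to the left of their band and the G2/M genes (median 0.54) to the right of theirs.

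Control probe sets gave a technical comparison of the 2 arrays. The 18 probe sets of the bacterial and phage spike-in transcripts had a median log2 ratio of -0.01 ± 0.14 (SD over 18 probe sets), with a range from -0.40 to 0.08. The 14454 other entering probe sets of the same signal range had a median of 0.23. The ratio of 3′ to 5′ probe set signal was 1.97 on the control array and 1.93 on the CTNNB1 siRNA array for ACTB, and 1.16 and 1.14 for GAPDH. Probe sets for ribosomal RNA differed more. Those named M27830 read 1580 with control siRNA and 368 with CTNNB1 siRNA (AFFX-M27830_M_at, a log2 ratio of -2.10) and 496 and 218.5 (AFFX-M27830_5_at, -1.18), while the 3 named M10098, all dim, had log2 ratios of -0.11, 0.32 and 0.09. Why the M27830 signals differ was not tested.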

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

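Part of the table belongs to no gene comparison. Among the 4655 entering probe sets without a single gene symbol, 177 (3.8%) were at least 2-fold higher and 158 (3.39%) at least 2-fold lower with CTNNB1 siRNA. They were flagged only because they lie outside the gene comparisons. The higher ones lie above the control array by the way they were counted, and the 2 directions are close in number. Over all 27151 entering probe sets, 946 were higher and 656 lower. The difference was not tested.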

How the results depend on the processing

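With 1 array per group no replicate could be left out. No paired analysis was possible because each group held 1 array. CTNNB1 stayed lower in all 10 alternative settings and moved beyond the probe set SD only with the median over its probe sets (-0.97). The median of the core Wnt targets stayed negative in all 10. It moved to -0.36 with scaling to a common median (13 genes, SP5 lost), where both members and values differ. It moved to -0.44 with no filter (18 genes) and -0.37 with the filter at the 75th percentile (7 genes). In these 2 filter settings only the members differ. The counts were the least stable values. Lower and higher genes numbered 953 and 1409 at 1.5-fold, 53 and 44 at 3-fold, 656 and 946 when probe sets were counted, 183 and 472 with scaling to a common median, 1271 and 721 with no filter, 34 and 139 with the filter at the 75th percentile, 477 and 679 with the probe set of largest ratio, and 456 and 164 when centred on the median ratio (chosen after seeing the data). With the floor at the median, 160 genes were lower. After quantile normalization the counts were 283 and 210, and 239 and 187 of those genes were also called without it. After loess they were 266 and 223, with 232 and 193 shared. The median of the stress response list turned to 0.10 with scaling to a common median, and COL1A1 to 0.055 with the median over its probe sets. Among values not past the rule or not standing apart, signs near 0 turned as well: the medians of 13 such lists had both signs over the settings, and NES went from 0.17 to -0.28 with the median over its probe sets and to -0.73 with the probe set of largest ratio. Of the remaining alternative values, 247 for lists and 1494 for named genes lay within the probe set SD of the reported value, and 1 and 26 lay beyond it. These counts are a weak check, since the floor and filter settings leave the value of most entering genes unchanged. For a list median the SD of a single probe set is also a wide bound. The junction list stayed within it while moving from the 2.72 to the 56.1 percentile with the probe set of largest ratio. Scaling to a common median and centring multiply an array by 1 factor, which moves nearly all log2 ratios by the same amount. The median of all genes was 0.15 as deposited, 0.29 with that scaling and 0.005 when centred. Under a fixed rule such a move shifts calls from 1 direction to the other. Why the counts differ after loess and quantile normalization was not tested. The SD between probe sets was 0.42 over all and 0.29 over bright ones.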

Other observations

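Lists added after the first results were seen described further gene groups, and their tests, like the tests on spike-ins and on the other probe sets of lower, of higher and of G2/M genes, were chosen after the pattern they follow. ERK output genes had a median above that of genes of matched signal, with members in both directions. Of 15 entering, IER3 (0.99), DUSP5 (0.95), HBEGF (0.91), PHLDA1 (0.83), SPRY2 (0.81) and SPRY4 (0.78) had the highest log2 ratios and ETV4 was the only one past 2-fold as deposited, downward (317 against 158.5). With scaling to a common median ETV4 (-0.87) did not pass, while IER3 (1.13), DUSP5 (1.09) and HBEGF (1.05) did, upward. The list's median was 0.42, at the 98.11 percentile of matched random lists (99.9 after loess). The higher FOSL1, JUN, PLAUR and PLAU (3-fold, 905 against 2717, named after its value was seen) led to this list, and whether they share a cause with it stays open. A wider rise of AP-1 components and targets was not seen in the added AP-1 list, which had a median of 0.21 at the 70.4 percentile over 11 genes, with HMGA1 at 0.75, FOS at -0.26 and HMGA2 at -1.10 (-0.41 with the median over its probe sets).

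ATF4 targets outside the first stress list were also low relative to genes of matched signal. NUPR1 had a log2 ratio of -1.05 (-0.91 with scaling to a common median), PCK2 of -0.84 and ALDH1L2 of -0.49 (0.89 with its probe set of largest ratio). STC2 was 490 against 246, but its log2 ratio was only -0.51 with the median over its probe sets. The amino acid transporter genes SLC3A2 (0.93) and SLC7A5 (0.81) were positive. The median was -0.11 over 20 genes, 12 of them below 0, at the 0 percentile (below all 10000 random lists). A wider fall of ATF4 targets would give such a position, but the list was chosen after TRIB3, CHAC1 and ASNS were seen to be lower. It does not tell what lowered them, and the ATF4 transcript itself was not lower (0.33). Differences in medium or density between the cultures stay open. NRF2 targets lay at the 0.15 percentile with a median of 0.03 over 16 genes, with AKR1C3 at -1.33, OSGIN1 at -0.69, HMOX1 at 1.30 and NQO1 at 0.01. AKR1C1 and AKR1C3 are paralogs that can share signal. PPAR targets did not follow PDK4 and SLC27A2, with a median of 0.14 at the 18.6 percentile over 11 genes.

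The ratio was higher for brighter genes, from a median of -0.23 in the dimmest decile of genes to 0.27 in the brightest. A gain of scanning or scaling common to all probe sets is argued against by the spike-ins, whose median was -0.0099 (SD 0.14) where other probe sets of the same signal range had 0.23; all 18 lay below the median of probe sets of the same signal decile. This concerns the level and not the trend. The 18 probe sets are repeated readings of the bioB, bioC, bioD and cre transcripts. They are not independent, so their SD and the interval below may be too narrow. The 9 brighter spike-ins exceeded the 9 dimmer ones by a median log2 ratio of 0.10 (bootstrap 95% interval -0.025 to 0.303), against 0.060 for probe sets of the same signals, so an effect of hybridisation, scanning or summarisation that depends on signal cannot be told apart, as the interval holds both 0 and 0.060. A different amount or amplification of labelled RNA cannot be told apart from a true shift, since no RNA amount was used here. The trend does not account for the lower core Wnt targets, which lay below all random lists matched on signal. Their percentile after loess, also 0, adds little to that matching.

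The G2/M genes were higher together. Their 20 entering probe sets that did not represent the gene came from 14 genes. Of these probe sets, 18 lay above the median of probe sets of the same signal (90%, exact 95% interval 68.3 to 98.8). This argues against error of a single probe set. The interval treats the probe sets as independent and may be too narrow. Probe sets of 1 gene can overlap, and the genes can vary together. The trend with signal is argued against as well, since the random lists were matched on signal. The percentile after loess, also 100, adds little to that matching. The growth state of the 2 cultures, unrelated to CTNNB1, cannot be told apart from an effect of the siRNA with 1 array per group.

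For the 2-fold calls, error of a single probe set would leave the other probe sets of the same genes near those of equal signal. The 45 of 298 lower genes with other entering probe sets had a median excess of -0.40 (bootstrap 95% interval -0.63 to -0.11). The 116 such genes among the 287 higher ones had 0.48 (0.37 to 0.58). For these genes, this argues against error as the whole cause. Genes without another entering probe set are not covered, and 255 of the 298 lower genes lay in the 3 dimmest deciles. The other probe sets themselves had medians of -0.51 and 0.56, and 12 of the 45 and 22 of the 116 also passed 2-fold. A bound set beforehand, 1 probe set SD from the median of all genes, was passed by the lower genes only, so how much of each fold is error stays open, and overlapping probe sets are not independent.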
